A study of Homo sapiens with 4 samples.

How the data were processed

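Polyadenylated RNA of FaDu and UMSCC47 cells treated with DMSO or with Aza and TSA was sequenced from 1 stranded library per group, 4 libraries in all, and the 4 groups were taken from the sample labels. The authors deposited 1 table with a row per gene symbol and a column of FPKM per library, per the file headers. Reads were processed with TopHat 1.3.2 and Cufflinks 2.0.2 on hg19, per the submitters' processing notes. The annotation, the filters and any scaling between libraries are not given in the sources used here. Vehicles were DMSO for Aza and ethanol for TSA, per the labels' protocols. The source names of the controls read DMSO only.

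The columns were first compared with each other. The UMSCC47 columns did not follow the gene names of their rows, by the levels of 34 housekeeping genes, by rank correlation with the FaDu columns and by the correlation of neighbouring rows, which was 0.370 in each FaDu column and 0.0213 and 0.0229 in the UMSCC47 columns. No order was guessed for them. They were used only as whole distributions. The comparisons that needed them were planned and were left out: genes differing in UMSCC47, genes differing in both lines, the overlap of the lines, differing responses, the difference of the lines at baseline, and silent genes classed by the other line.

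For FaDu, 45 repeated rows were summed to 25548 gene symbols. The change of a gene was log2((treated FPKM + 1)/(DMSO FPKM + 1)), which understates the change of genes at low levels, and a gene counted as measured with at least 1 FPKM in either library, which a difference can itself bring about, so that medians over all members are given where they are over 1.5 times smaller. Genes were called higher or lower at a 2-fold difference on this scale, and switched on when under 0.1 FPKM in the DMSO library and at 1 FPKM or more in the treated library. By these rules a measured gene listed at 0 in the DMSO library is always called higher. With 1 library per group no p-value is given. The FPKM were not rescaled. These rules, the gene lists and the rule for named genes were fixed before the data were examined. The genes named are the 8 with the largest and the 8 with the smallest change, up to 4 members with the widest change from each gene list, and the methyltransferases DNMT1, DNMT3A and DNMT3B. The rule ranked list members by both lines, and FaDu alone was used. Genes of microRNAs, small nucleolar, Cajal body, small nuclear and Y RNAs and similar classes, called short RNA genes here, XIST and Y-linked genes were left out of the rankings. The SNAR genes, which are also short RNAs, were not among these classes and stayed in. Genes named outside the rule, among them GAPDH, SPIC and SNAR-F, were chosen after their values were seen.

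Gene lists were written from general knowledge with older symbols matched: cancer-testis antigens, germ-cell genes, interferon-stimulated genes, antigen presentation, cytokines and chemokines, G2/M and mitosis genes, DNA replication genes, p53 target genes, CDK inhibitors, replication-dependent and replication-independent histone genes, DNA methylation enzymes and readers, histone deacetylases, metallothioneins, keratinocyte differentiation genes, basal keratinocyte genes, epithelial junction genes, mesenchymal genes, endothelial markers, leukocyte markers, neuronal genes, imprinted genes, genes reported silenced by methylation, KRAB zinc-finger genes, HOX genes, cholesterol biosynthesis genes, glycolysis genes, oxidative phosphorylation genes, ribosomal protein genes, ribosome biogenesis and MYC target genes, unfolded-protein and ATF4 stress genes, heat-shock genes, NRF2 target genes, apoptosis regulators and housekeeping genes. For each list the median log2 change of its measured members was placed among the medians of 10000 random lists of the same size. These were matched in 20 bins of mean expression over both libraries. That mean includes the change, so random genes need not share the level of the list in the DMSO library. The percentile describes these libraries and is not a test across replicates. A list was called outside below percentile 2.5 or above 97.5.

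The relative depth of the FaDu libraries was read from 56 short RNA genes. The FPKM worth of 1 read in the treated library was 1.00 times that in the DMSO library, a value at which 44.6% of the genes had ratios of whole numbers up to 6 within 0.01%, against a median of 0% at other values tried. GC content and length came from GENCODE release 29 transcripts, on another genome build than the files, so no coordinates were used. The trend of the log2 change on GC content, or on log2 length, was fitted by lowess with a fraction of 0.3 over genes at 5 FPKM or more in both libraries and subtracted from every gene with a value. This correction can be too strong for genes near 0 FPKM, whose change the pseudocount already shrinks.

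The other settings tried were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, scaling to TPM, the highest row per symbol, leaving out short RNA genes, random lists without matching, and limits of 0.5 and 2 FPKM for switching. Added after the data were seen were GC and length correction, median-ratio scaling over the 2 FaDu libraries, 1 member per cancer-testis family, and another level and scaling for the UMSCC47 columns. The procedure was tested on simulated data for the FaDu comparison. Among 12062 simulated genes, all 100 raised 4-fold and 91% of the 100 lowered 4-fold were recovered, and 4% of unchanged lists fell outside the range. The simulated noise was set at an SD of 0.2 on the log2 scale, which no replicate measures here, so the simulation checks the calculation and not the rate of false calls. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.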

Results

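Messenger RNA was measured by stranded RNA-seq in 2 established head and neck squamous carcinoma cell lines, FaDu, which comes from a tumour of the hypopharynx, and UMSCC47, an HPV16-positive line from the tongue. Each line was given vehicle, labelled DMSO only, or a combination of 5-aza-2'-deoxycytidine (Aza), a nucleoside that traps DNA methyltransferases and lowers DNA methylation, and trichostatin A (TSA), an inhibitor of histone deacetylases. FaDu received 5 µM Aza on days 1 to 3 and 100 nM TSA on day 3. UMSCC47 received 3 µM Aza and 300 nM TSA on the same days. There was 1 library in each of the 4 groups, so no difference given here has a replicate check. Expression is in FPKM over 25593 rows of gene symbols, and the columns sum to 491963 FPKM (FaDu DMSO), 516692 (FaDu treated), 567004 (UMSCC47 DMSO) and 526975 (UMSCC47 treated). FPKM do not give the number of reads, so absolute depth is unknown. Of 56 short RNA genes, 44.6% had ratios of whole numbers between the FaDu libraries, as values that step in single reads would. At that fit the FPKM worth of 1 read differed between the FaDu libraries by 0.02%. Any scaling between libraries is unknown, so this need not measure depth.

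Genes that every cell uses were at their usual high levels in both FaDu columns and not in either UMSCC47 column. GAPDH, a glycolytic enzyme, was listed at 2590 and 2971 FPKM in the DMSO and treated FaDu columns, and at 0.290 and 0.177 in the UMSCC47 columns. The cytoskeletal gene ACTB was listed at 641 and 1529 FPKM in FaDu and at 1.25 and 0.766 in UMSCC47. The highest value of the UMSCC47 DMSO column, 18491 FPKM, stood on the row of SPIC, a transcription factor of macrophages, which was listed at 0 in the other 3 columns. Of 34 housekeeping genes, 33 reached 10 FPKM in each FaDu column, against 13 and 7 in the UMSCC47 DMSO and treated columns, where rows in random order would give 8.07 and 7.88. Of 452 genes at 100 FPKM or more in both FaDu columns, 49 and 52 were above 50 FPKM in the UMSCC47 columns, against 28.8 and 26.6 for random order, so the order was not wholly random. The Spearman correlation across rows was 0.908 between the FaDu columns. It was 0.124 between the UMSCC47 columns and 0.110 to 0.121 between the lines. The UMSCC47 columns therefore give no values for named genes here, and the comparisons of genes are those within FaDu.

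**Figure D1:**
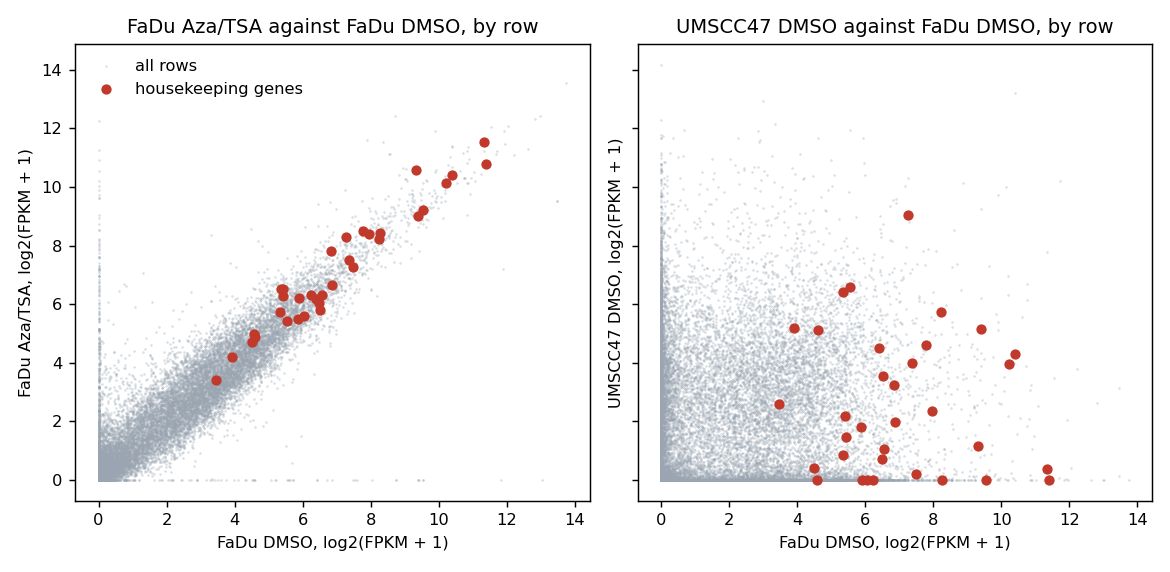
Expression of each row, log2(FPKM + 1), in the treated FaDu column (left) and the UMSCC47 DMSO column (right) against the FaDu DMSO column, with 34 housekeeping genes in red. The rows follow each other between the FaDu columns (Spearman 0.908) and hardly at all between the lines (0.110).

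The FaDu comparison asks which genes differ in expression after inhibition of DNA methylation and histone deacetylation. In the treated FaDu library, 46 of 54 cancer-testis antigens, 18 of 44 germ-cell genes, 22 of 51 interferon-stimulated genes and 28 of 37 replication-dependent histone genes were at least 2-fold higher. Lists of unfolded-protein and ATF4 stress genes and of NRF2 targets had lower medians than random lists. Of 13558 genes measured at 1 FPKM or more in either library, 2178 (16.1%) were at least 2-fold higher in the treated library and 706 (5.21%) at least 2-fold lower, on the log2(FPKM + 1) scale. These counts depend on the setting, with 910 higher and 572 lower after GC correction, 893 and 253 with a pseudocount of 5, and 2681 and 1152 with TPM scaling. At 4-fold the counts were 496 and 91. There were 524 genes that went from under 0.1 FPKM to 1 FPKM or more, which is called switched on here, and 67 that went the other way. The switched-on genes had a median of 3.41 FPKM in the treated library, and 155 of them reached 10 FPKM. The change of a gene followed the GC content of its transcript, with a Spearman correlation of 0.67 across 7127 genes, so each list below is also given after the GC trend was subtracted. Counts of list members below are of those measured, unless the whole list is named.

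Outside the short RNA classes left out of the ranking, the 8 genes with the largest change were all listed at 0 in the DMSO library. They were SNAR-G1 (194 FPKM when treated), SNAR-B1 and SNAR-B2 (159 each), SNAR-C3 (138), SNAR-C4 (133) and SNAR-E (89.8), near-identical short RNAs, followed by MAGEB2 (87.2), a cancer-testis antigen, and DAZL (79.6), an RNA-binding protein of germ cells. Reads of the SNAR copies cannot be told apart, and an FPKM of so short an RNA can rest on few reads: the related SNAR-F was listed at 15.5 and 155 FPKM. At the lower end, CP, which encodes the copper protein ceruloplasmin, was 44.5 FPKM in the DMSO library and 1.25 in the treated library, a 35.5-fold difference. The other 7 genes at that end were uncharacterised loci whose symbols have no match in the current RefSeq table. Among them LOC100509105 went from 48.0 FPKM to 1.52e-07 and LOC100506732 from 47.8 to 7.44e-06. Values so close to 0 were found in 65 of the 706 lower genes, which were under 0.01 FPKM in the treated library. FPKM this small are estimates and not counts of reads. Such falls need not be falls in expression, which was not tested.

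Cancer-testis antigens, which are normally expressed in germ cells and often silenced by promoter methylation elsewhere, gave the widest difference. Of 47 measured members, 46 were at least 2-fold higher in the treated library and none lower. They belonged to 21 families, each with a member at least 2-fold higher. Of the measured members 31 were listed at 0 in the DMSO library, and 41 of the 54 genes in the list were switched on. Those 31 could only be called higher once measured, so the counts of members and families rest partly on the filter. Over all 54 genes, measured or not, the median was 3.14 (percentile 100). MAGEB2, PAGE5 (61.3 FPKM) and PAGE2 (57.4 FPKM) were listed at 0 in the DMSO library, and PAGE2B was 0.207 FPKM there and 65.8 when treated. The list's median log2 change was 3.41, above all 10000 random lists of the same size and mean expression over both libraries (percentile 100), or 45 higher, 0 lower, median 3.07 and percentile 100 after GC correction. A gene at 0 in the DMSO library has the widest change possible at its mean. This percentile therefore does not set the antigens apart from other genes silent in the DMSO library. Germ-cell genes had a median of 2.16 (percentile 100), with 18 of 23 measured members higher and 1 lower (18 higher, 0 lower, median 2.34 and percentile 100 after GC correction). Among the 23 measured, 11 were listed at 0 in the DMSO library and so could only be called higher. Over all 44 germ-cell genes, measured or not, the median was 0.88 (percentile 100). MAEL, a piRNA pathway protein, was listed at 0 and then at 14.5 FPKM, SYCP3, a part of the synaptonemal complex, went from 0.152 to 13.9 FPKM, and the testis tubulin TUBA3D from 0.133 to 12.4 FPKM. The cancer-testis and germ-cell lists supplied 54 of the 524 switched-on genes. Members of these families share near-identical sequence, so the value of a single copy is uncertain.

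**Figure D2:**
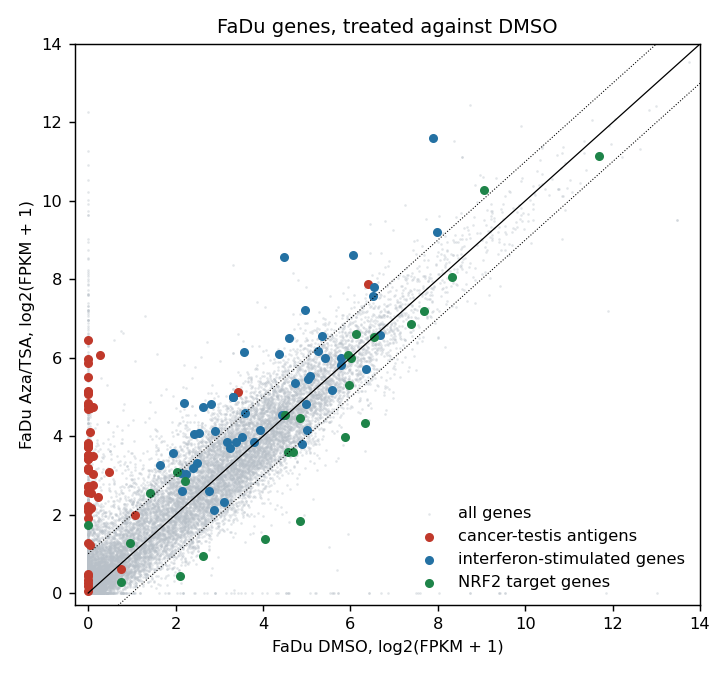
Expression of each gene in the treated FaDu library against the DMSO library, log2(FPKM + 1), 1 library each. The solid line marks equal expression and the dotted lines 2-fold differences. Cancer-testis antigens (red), measured or not, lie along the left edge, with 31 of the 47 measured at 0 in the DMSO library. Interferon-stimulated genes (blue) mostly lie above the solid line, with 22 of 51 at least 2-fold higher.

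Interferon-stimulated genes had a median log2 change of 0.80 (percentile 100), with 22 of 51 members at least 2-fold higher and 1 lower (21 higher, 1 lower, median 0.75 and percentile 100 after GC correction). IFI27 was 237 FPKM in the DMSO library and 3094 in the treated library, and IFI6 was 21.4 and 376 FPKM. The antiviral GTPase MX1 was 10.9 and 69.4 FPKM, and IRF7, the transcription factor that drives interferon production, was 3.59 and 27.7 FPKM. In the antigen presentation list of 28 genes, 9 of 20 measured members were higher and 1 lower, with a median of 0.90 (percentile 99.98), or 4 higher, 1 lower, median 0.40 and percentile 99.9 after GC correction. HLA-B was 103 FPKM in the DMSO library and 407 in the treated library, HLA-F 5.72 and 23.3, the peptide transporter TAP1 9.35 and 38.2, and the class II invariant chain CD74 0.961 and 10.9. Of 25 measured cytokines and chemokines, from a list of 30, 13 were higher and 5 lower (median 1.06, percentile 100, or 11 higher, 3 lower, median 0.98 and percentile 100 after GC correction). IL24 was 0.378 FPKM in the DMSO library and 14.2 when treated, CCL20 was 7.13 and 59.7, and IL32 was 0.607 and 9.06. IL11 was listed at 0 and then at 9.10 FPKM.

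Of the replication-dependent histone genes, 28 of 33 measured members were at least 2-fold higher in the treated library and none lower, with a median of 1.81 (percentile 100, or 25 higher, 1 lower, median 1.46 and percentile 100 after GC correction). The libraries hold polyadenylated RNA, and the measured members had a median of 1.68 FPKM in the DMSO library. Whether RNA of these genes without a poly(A) tail differed was not measured. HIST1H2BC was 4.45 FPKM in the DMSO library and 53.7 in the treated library, HIST1H2BG 3.48 and 37.5, HIST1H4H 2.82 and 31.3, and the linker histone gene HIST1H1C 30.5 and 221. Of 10 replication-independent histone genes none was at least 2-fold higher and 1 lower, H1F0 at 341 and 155 FPKM (list median −0.01, percentile 31.1). After GC correction that list lay below the random lists (0 higher, 1 lower, median −0.40, percentile 1.2). In the list of DNA methylation enzymes and readers 1 of 14, MBD3 at 7.91 and 22.6 FPKM, was at least 2-fold higher (median 0.22, percentile 72.6, or 0 higher, 0 lower, median 0.14 and percentile 84 after GC correction). The maintenance methyltransferase DNMT1 was 25.6 FPKM in the DMSO library and 43.5 in the treated library, DNMT3A 3.18 and 4.01, and DNMT3B 4.66 and 9.32. Of 17 histone deacetylases 4 were higher and 1 lower, with a median of 0.26 (percentile 66.1) whose sign flipped on correction (0 higher, 3 lower, median −0.17 and percentile 13.4 after GC correction). HDAC7 was 6.04 and 18.1 FPKM, and SIRT5 was 7.13 and 2.05.

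The medians of the ATF4 and NRF2 lists lay below those of random lists, and the medians of metallothioneins and heat-shock genes above. In the unfolded-protein and ATF4 list 10 of 29 members were at least 2-fold lower and 2 higher (median −0.30, percentile 0.620, or 0 higher, 12 lower, median −0.87 and percentile 0 after GC correction). The cystine transporter SLC7A11 was 27.8 FPKM in the DMSO library and 2.58 in the treated library, the serine synthesis enzyme PSAT1 110 and 22.9, and asparagine synthetase (ASNS) 181 and 50.9. ATF5 went against them, at 9.24 and 33.8 FPKM. Of 25 NRF2 target genes, 7 were lower and 4 higher (median −0.40, percentile 0.170, or 1 higher, 9 lower, median −0.50 and percentile 0.02 after GC correction). SLC7A11 is in both lists. AKR1C1, an aldo-keto reductase, was 15.6 and 1.58 FPKM, the glutathione synthesis enzyme GCLC 79.4 and 19.2, and ALDH3A1 57.3 and 14.8. The metal-binding metallothioneins, 13 in the list, were higher in 6 of 9 measured members and lower in none (median 1.23, percentile 99.7, or 4 higher, 0 lower, median 0.78 and percentile 99.5 after GC correction). MT2A was 212 FPKM in the DMSO library and 742 in the treated library, and MT1G was 1.09 and 9.82. Of 15 heat-shock genes 4 were higher and none lower (median 0.63, percentile 98.7, or 2 higher, 0 lower, median 0.40 and percentile 98.8 after GC correction). HSPB8 was 0.563 and 4.60 FPKM, and HSPB1 was 137 and 276. With only genes at 5 FPKM or more, the metallothionein and heat-shock medians fell inside the range of random lists, at percentiles 92.8 and 94.2, and the heat-shock genes did so against unmatched random lists (96.0).

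**Figure D3:**
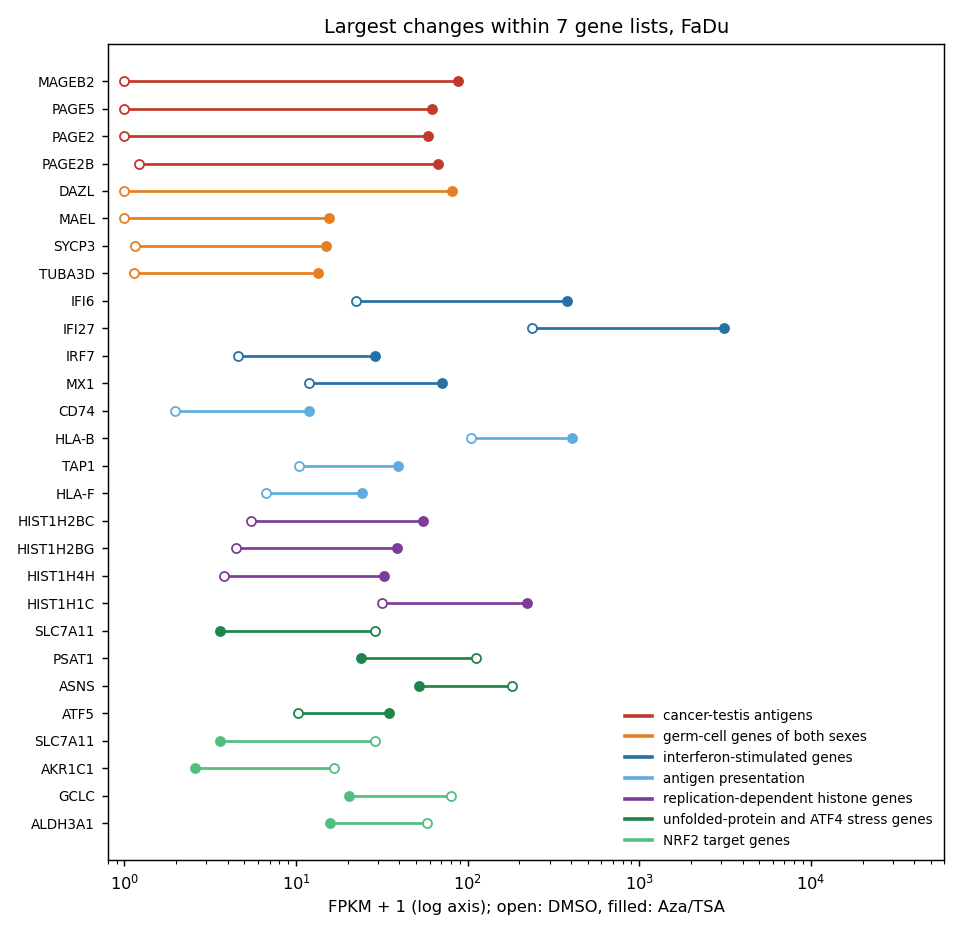
The 4 members with the widest change in each of 7 gene lists, as FPKM + 1 on a log axis in the FaDu DMSO library (open circles) and the treated library (filled circles). SLC7A11 belongs to 2 of the lists and is drawn in each. IFI27 reached 3094 FPKM when treated, while SLC7A11, PSAT1, ASNS, AKR1C1, GCLC and ALDH3A1 were lower when treated.

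Markers of squamous epithelium went in different directions. Of 25 keratinocyte differentiation genes 12 were higher and 1 lower in the treated library (median 0.98, percentile 99.98, or 8 higher, 2 lower, median 0.35 and percentile 98.8 after GC correction). Over all 46 genes of that list the median was 0.25 (percentile 99.8). The cornified envelope gene SPRR2D was listed at 0 and then at 17.9 FPKM, SBSN was 0.115 and 17.3, and S100A7 was 0.509 and 8.27. In the basal keratinocyte list 6 of 24 were higher and 3 lower (median 0.44, percentile 96.96, or 0 higher, 5 lower, median −0.01 and percentile 40 after GC correction). TP63, the master regulator of squamous identity, was 73.7 FPKM in the DMSO library and 23.2 in the treated library, and the basal keratin KRT5 was 687 and 226, while the nerve growth factor receptor NGFR was higher, at 1.91 and 7.90. Of 32 epithelial junction genes 6 were higher and 3 lower (median 0.16, percentile 65.1, or 0 higher, 3 lower, median 0.03 and percentile 54.7 after GC correction), with the desmosomal cadherin DSG3 at 22.1 and 3.16 FPKM and the tight junction gene CLDN1 at 111 and 24.4 lower, and the protease inhibitor SPINT1 at 26.5 and 86.2 and the transcription factor OVOL1 at 3.05 and 11.5 higher. Mesenchymal genes were higher in 11 of 19 measured members and lower in 2 (median 1.22, percentile 99.99, or 7 higher, 3 lower, median 0.73 and percentile 99.99 after GC correction), and over all 36 the median was 0.34 (percentile 99.7). MYL9 was 4.21 and 43.7 FPKM, TAGLN 0.686 and 13.2, FN1 0.647 and 9.31, and the transcription factor SNAI1 0.475 and 6.53.

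Some genes of other lineages were also higher, mostly at low levels, while most neuronal, leukocyte and endothelial genes of the lists stayed under 1 FPKM in both libraries. Neuronal genes were higher in 13 of 22 measured members and lower in 1 (median 1.27, percentile 99.99, or 6 of 21 higher, 0 lower, median 0.56 and percentile 99.4 after GC correction), among them UCHL1 at 0.777 and 27.3 FPKM and the neurofilament gene NEFH, listed at 0 and then at 4.89. With only genes at 5 FPKM or more the neuronal list lay inside the random range, at percentile 91.6. Over all 50 neuronal genes the median was 0.34 (percentile 99.97). Of 22 leukocyte markers 6 were measured and 5 of these were higher (median 1.56, percentile 99.9, or 4 higher, 0 lower, median 1.23 and percentile 99.8 after GC correction), with CORO1A at 0.425 and 10.7 FPKM, and over all 22 the median was 0.24 (percentile 99.6). Of 14 endothelial markers 4 were measured and all 4 were higher (median 1.34, percentile 98.3), such as EGFL7 at 5.13 and 19.3 FPKM, but none was at least 2-fold higher after GC correction (median 0.69, percentile 95.4). The endothelial list also fell inside the random range with a pseudocount of 0.1 (percentile 94.3) and with only genes at 5 FPKM or more (94.4), and over all 14 its median was 0.15 (percentile 98.4). Of 15 imprinted genes 6 were higher and 1 lower (median 0.72, percentile 96.7, or 3 higher, 1 lower, median 0.41 and percentile 98.1 after GC correction). NNAT was 0.704 and 14.1 FPKM, and the noncoding RNA MEG3 was listed at 0 and then at 4.74. Over all 26 imprinted genes the median was 0.16 (percentile 91.3). Genes reported as silenced by methylation in carcinomas had 7 of 32 measured members higher and none lower (median 0.46, percentile 90.2, or 4 higher, 3 lower, median 0.19 and percentile 91.1 after GC correction), with TFPI2 at 45.1 and 191 FPKM, SOCS1 at 0.177 and 2.65 and RASSF1 at 1.72 and 5.87. Over all 58 genes that list had a median of 0.25 and lay above the random lists (percentile 99.7).

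Most G2/M and DNA replication genes lay within 2-fold. So did 16 of 28 p53 targets and 4 of 7 CDK inhibitors, with the rest in either direction. Of 40 G2/M and mitosis genes 1, CENPF at 40.2 and 19.6 FPKM, was at least 2-fold lower and none higher. The list's median was −0.25 (percentile 0.2), and after GC correction it lay inside the random range (0 higher, 0 lower, median −0.09, percentile 8.28). Of 41 DNA replication genes 3 were higher and 3 lower (median 0.31, percentile 93.4, or 1 higher, 0 lower, median 0.01 and percentile 48.9 after GC correction), with E2F1 at 4.82 and 13.5 FPKM and the clamp loader subunit RFC4 at 47.4 and 21.3. Of 28 p53 target genes 8 were higher and 4 lower, and the median of −0.00 (percentile 33.9) differed in sign from the mean of 0.27 (5 higher, 3 lower, median 0.00 and percentile 52.1 after GC correction). That median turned above 0 with a pseudocount of 0.1, no filter and TPM scaling, and was 0.16 (percentile 67.1) with a filter at 5 FPKM. The CDK inhibitor CDKN1A was 16.2 FPKM in the DMSO library and 66.1 in the treated library, TP53I3 2.06 and 14.4, and GADD45A 157 and 49.6. Of 7 CDK inhibitors 2 were higher and 1 lower (median −0.38 and mean 0.23, percentile 7.15, or 2 higher, 3 lower, median −0.08 and percentile 31.9 after GC correction), and CDKN2D was 1.90 and 23.6 FPKM. Of 23 apoptosis regulators 4 were higher and 3 lower (median 0.16, percentile 66.2), and the median flipped on correction (1 higher, 3 lower, median −0.19 and percentile 5.51 after GC correction). Over all 29 the median was 0.05 (percentile 57.1). The death ligand gene TNFSF10 was 50.3 and 9.25 FPKM, and the BH3-only gene BIK 10.9 and 41.6.

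Most genes of growth and core metabolism lay within 2-fold of their levels in the DMSO library. None of 34 oxidative phosphorylation genes passed 2-fold in either direction (median 0.15, percentile 61.2, or 0 higher, 0 lower, median 0.02 and percentile 41.8 after GC correction), and of 20 glycolysis genes 1 did, the lactate exporter SLC16A3 at 15.1 and 71.4 FPKM (median 0.23, percentile 75.3). The glycolysis median flipped on correction (1 higher, 1 lower, median −0.16 and percentile 8.45 after GC correction). Of 34 ribosome biogenesis and MYC target genes 4 were higher and 1 lower (median 0.34, percentile 94.1, or 0 higher, 1 lower, median 0.16 and percentile 90.1 after GC correction), the lower member being MYC itself at 258 and 91.3 FPKM. Of 59 ribosomal protein genes 1 was higher and none lower (median −0.06, percentile 5.81, or 0 higher, 2 lower, median −0.28 and percentile 0 after GC correction). Of 25 cholesterol biosynthesis genes 3 were lower and none higher (median −0.16, percentile 9.02, or 0 higher, 3 lower, median −0.32 and percentile 0.31 after GC correction), with MSMO1 at 26.6 and 10.5 FPKM. Among 34 housekeeping genes 4 were higher, ACTB, VCP, POLR2A and TUBA1B, and none lower (median 0.11, percentile 47.3, or 0 higher, 1 lower, median 0.07 and percentile 60.1 after GC correction). Of 82 KRAB zinc-finger genes, which include repressors of transposable elements, 6 were higher and none lower. Their median of −0.04 (percentile 3.64) flipped on correction (9 higher, 0 lower, median 0.20 and percentile 99.1 after GC correction), turned above 0 with no filter and with a filter at 5 FPKM, and lay below the random lists with TPM scaling (percentile 2.26) and length correction (1.59). ZNF154 was 0.0937 and 2.48 FPKM. Of 31 HOX genes 3 were higher and 1 lower, and their median of 0.05 (percentile 29.6) also flipped on correction (0 higher, 3 lower, median −0.43 and percentile 0.03 after GC correction) and turned below 0 with TPM scaling, length correction and a filter at 5 FPKM.

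**Figure D4:**
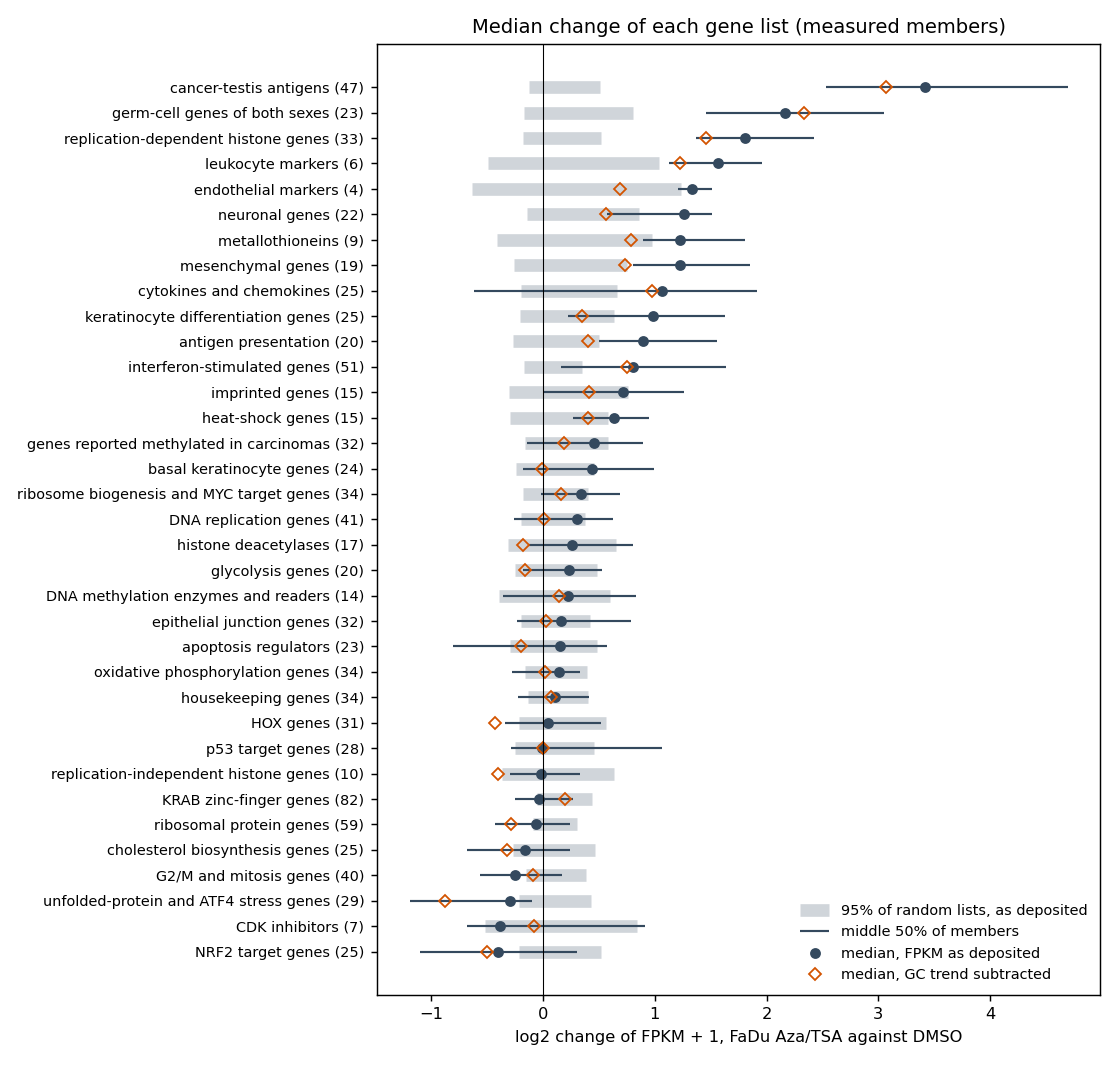
Median log2 change (FaDu treated against DMSO, log2 of FPKM + 1) of each of 35 gene lists, with the number of measured members in brackets. Filled circles are medians as deposited with bars for the middle 50% of members, grey bands hold 95% of random lists for the values as deposited, and open diamonds are medians after GC correction. Cancer-testis antigens stand highest, at 3.41, and 3.07 after correction.

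In all, 13 of the 35 lists lay above the 95% range of random lists and 3 below it. By chance 1.75 would fall outside if the genes of a list varied as independently as random genes. Genes of a list can vary together, so more can fall outside without an effect of treatment. After GC correction 14 lay above and 6 below, among them 12 of the 13 and 2 of the 3, and 6 lists lay outside only after it. The trend itself ran from a median log2 change of −0.45 in the fifth of genes with the lowest GC content to 0.79 in the fifth with the highest, among 7127 genes at 5 FPKM or more in both libraries. A GC value was held for 12526 of the measured genes, of which 2020 were at least 2-fold higher and 612 lower as deposited. Subtracting the trend left 910 of the 12526 higher, 827 of them among the 2020, and 572 lower, 305 of them among the 612. Over the same genes the share of higher among all differing genes went from 76.7% to 61.4%, and the median change from 0.13 to 0.01. Transcript length showed a much weaker relation (Spearman −0.06).

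**Figure D5:**
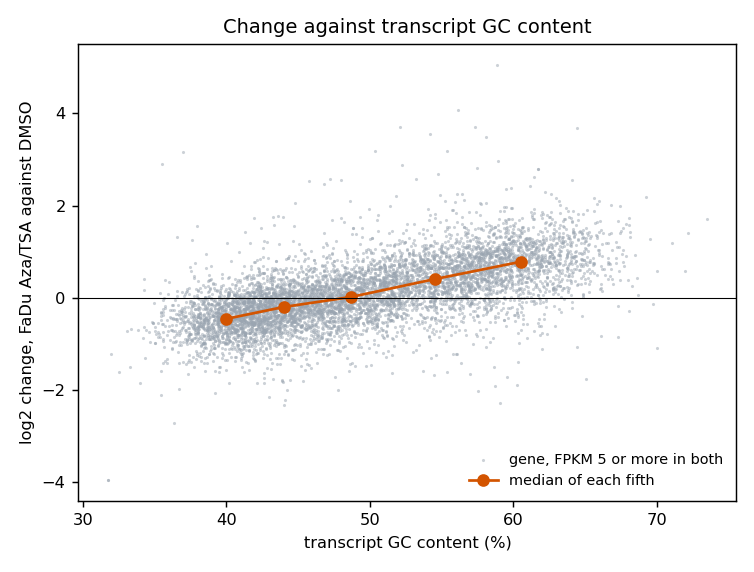
Log2 change of each gene (FaDu treated against DMSO, log2 of FPKM + 1) against the GC content of its transcript in percent, for genes at 5 FPKM or more in both libraries. Orange points are the medians of 5 equal groups of genes by GC content, from −0.45 to 0.79.

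Whole columns could be compared in both lines, taking the column labels as given, since they do not need gene names. In FaDu, 12074 rows reached 1 FPKM in the DMSO column and 13034 in the treated column, and 7806 and 6086 rows were listed at 0. In UMSCC47, 12883 and 13362 rows reached 1 FPKM, and 7566 and 5908 were listed at 0. At 10 FPKM the order differed between the lines, with 5721 and 6196 rows in FaDu and 6071 and 5928 in UMSCC47. The 10 highest rows held 16.1% of all FPKM in the FaDu DMSO column and 10.1% in the treated column, and 11.3% and 17.04% in UMSCC47.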

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

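The tests on the UMSCC47 columns, on relative depth and on abundant genes were chosen after the results were seen; the test of GC content on the switched-on genes was written before. Between the UMSCC47 columns, which carry no usable gene names, 1658 more rows were above 0 in the treated column than in the DMSO column. Among FaDu short RNA genes, which the rankings leave out, 51 more reached 1 FPKM in the treated library than in the DMSO library, 217 against 166.

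The UMSCC47 values did not go with the gene names beside them. The median of the housekeeping genes stood at percentile 60.7 of the UMSCC47 DMSO column, while in FaDu DMSO it stood at 97.3. A constant shift of the rows is argued against by a highest Pearson correlation of 0.0827 over all 25593 shifts. Another cell line or a mislabelled sample with its rows in order is argued against by the housekeeping genes. Of these 13 of 34 reached 10 FPKM, while any human cell expresses nearly all of them. With rows out of order these values cannot show which sample a column came from. The values may be those of the right libraries in another row order, though not a wholly random one, since 49 of 452 genes high in FaDu were above 50 FPKM there, against 28.8 for random rows. Which order cannot be recovered here, and no biological explanation was tested.

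More genes were detected in the treated FaDu library, 1720 more rows above 0 and 960 more at 1 FPKM. A deeper treated library is argued against by a difference of 0.02% in the FPKM worth of 1 read, provided that the FPKM were not scaled between the libraries. Abundant genes leaving more reads for the rest would raise all genes alike. The median log2 change of genes at 5 FPKM or more in both libraries was 0.05 (0.04799). The 10 highest rows held 16.1% of FPKM in the DMSO column and 10.1% in the treated column. Any such rise would therefore be small, and this median cannot tell it from none. The GC trend cannot be told apart from a gain of expression for part of these genes: after subtracting it, 77.2% of the 460 switched-on genes with a GC value stayed at least 2-fold higher, between the bounds set for either answer. An effect of Aza and TSA remains open, as untested.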

How the results depend on the processing

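GC and length correction, the median-ratio scaling and the settings for UMSCC47 were chosen after seeing the data. The count of higher genes, 2178, was 893 with a pseudocount of 5 and 910 after GC correction, which covers 12526 genes, 2020 of them higher before it. The count of lower genes, 706, was 1182 with a pseudocount of 0.1, 253 with a pseudocount of 5 and 1152 with TPM scaling. The 67 switched-off genes were 33 without short RNA genes, since 34 of them are short RNAs, and the 524 switched-on genes ranged from 439 to 698. The gain of 479 UMSCC47 rows at 1 FPKM became −143 at 10 FPKM and 804 with TPM scaling. TPM scaling raised every FaDu value above 0, since the columns summed to 491963 and 516692 FPKM before it, so the fixed pseudocount and floor weighed less. It raised the DMSO column more than the treated column, which lowers the ratio of treated to DMSO for every gene. With it 14937 genes were measured instead of 13558, all 706 lower genes stayed lower, and 2120 of the 2178 higher genes stayed higher. Apart from this and the short RNAs the cause was not tested. Of 1694 values recomputed for 172 named genes, 269 moved by 0.5 or more on the log2 scale, 148 of them with the pseudocount, and none of the genes called 2-fold reversed. Of 385 recomputed list medians 38 moved by more than the distance from the middle of the random range to its edge and no called one reversed. Of the 16 lists outside the random range, 11 stayed on the same side under all 11 alternatives. The others were G2/M (inside after GC correction), metallothioneins and neuronal genes (inside with a filter at 5 FPKM), heat-shock genes (that filter and unmatched lists) and endothelial markers (that filter, a pseudocount of 0.1 and GC correction). Outside only under an alternative were replication-independent histone, HOX, cholesterol and ribosomal protein genes (GC correction), KRAB zinc-finger genes (above with GC correction, below with TPM scaling and length correction), imprinted genes (GC, length, unmatched lists), basal keratinocyte genes (length) and genes reported silenced by methylation (no filter). No paired analysis was possible because each group has 1 library. The alternatives chosen for UMSCC47 alone, for both lines and for silent genes by the other line were not run, nor was median-ratio scaling over 4 libraries, since the UMSCC47 rows carry no usable names. With absolute depth unknown, no limit can be given for genes listed at 0.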

Other observations

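Genes named in the next paragraphs were chosen after their values were seen, as was the test of GC content within ribosomal and respiratory genes. The tests of GC content on single lists were written before their values were seen.

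Outside the gene lists, several single genes stood far apart in FaDu. KRT7, a keratin of simple epithelium, was 8.87 FPKM in the DMSO library and 327 in the treated library, 36.9-fold higher, and its log2 change of 5.06 was 4.38 after GC correction. The cystatin gene CST6 was 1.47 and 133 FPKM (log2 change 5.76, corrected 4.74), the short-chain dehydrogenase DHRS2 13.6 and 171 FPKM (3.56, corrected 3.17), and CYP24A1, which inactivates vitamin D, 3.54 and 55.1 FPKM (3.63, corrected 3.78). The metalloproteinase inhibitor TIMP1 was 24.6 and 287 FPKM, and the galectin LGALS1 was 86.6 and 682. The testis genes VCX (0.736 and 98.1 FPKM), VCX2 (0.220 and 43.5) and VCX3A (0.509 and 87.2) were higher together, as copies of near-identical sequence, and GTSF1, a partner of piRNA proteins, was listed at 0 and then at 44.1 FPKM.

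Lower in the treated library were PAX9 (51.95 and 9.90 FPKM) and ZNF750 (17.2 and 2.33 FPKM), transcription factors of squamous epithelium, with log2 changes of −2.28 and −2.45 that were −2.97 and −2.95 after GC correction. The glucuronosyltransferase UGT1A6 was 34.2 and 4.22 FPKM, and the tubulin tyrosine ligase TTL 9.17 and 0.0632. So low an estimate for TTL need not be a fall in expression, which was not tested. Within the lists, but outside the naming rule, the basal keratin KRT14 was 49.8 and 147 FPKM while KRT5 was 687 and 226. ISG15 was 65.9 and 394 FPKM, the cytokine IL6 12.5 and 77.6, and the ferritin light chain FTL 530 and 1241, against the direction of most NRF2 targets.

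A difference in the recovery of GC-rich transcripts between the libraries is a candidate explanation for part of the list changes. Within 93 ribosomal protein and oxidative phosphorylation genes, which are of even function, the Spearman correlation of change and GC content was 0.53 (0.5333), as such a difference needs, though a response of GC-rich genes to treatment is not excluded. The fitted trend is too small to be the whole cause for the cancer-testis antigens and the replication-dependent histone genes. Their medians were 3.41 and 1.81. The trend ran only from −0.45 to 0.79 between the groups of genes lowest and highest in GC content. The interferon-stimulated genes had a median GC content of 48.6%, against 49.9% for measured genes. Subtracting the trend moved their median little, from 0.80 to 0.75. Each of these lists stood at percentile 100 after correction. That could hardly have come out otherwise, so the percentile adds no evidence against the trend. The G2/M and mitosis genes went from a median of −0.25 (percentile 0.2) to −0.09 (percentile 8.28), because their transcripts are poor in GC (median 44.9%), and that call did not outlast the correction. An effect of Aza and TSA on these lists was not tested, which would need replicates, promoter methylation or each drug alone.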
